A study of Homo sapiens with 6 samples.

How the data were processed

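CUT&Tag was performed on MOLM13 cells with an antibody against ARID1B, an antibody against ARID2 and a rabbit IgG control. CUT&Tag tethers a transposase to an antibody bound to chromatin, so that sequencing adapters are inserted close to the bound protein and no fragmentation or immunoprecipitation step is needed. The labels give 2 libraries per antibody, 6 in all, and do not say whether these came from separate cultures. The deposited data used here are 2 peak lists, one per ARID antibody. The labels attach each list to both libraries of its antibody and to both IgG libraries.

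Per the submitters' processing notes, reads were aligned with Bowtie2 version 2.3.5 to hg19, and the contig names in the lists are those of hg19. The lists are named for the irreproducible discovery rate (IDR), a measure that keeps peaks ranked alike in a pair of replicates. The peak caller, the IDR threshold and the use made of the IgG libraries are not given in the sources used here. Each line of the deposited lists gives genome positions (a start and an end), a name and a score. The deposited score is 0 in every line of both lists (100% of 7756 and of 8146 lines) and no strand is given, so no peak height, enrichment, p-value or IDR accompanies a peak. Peak width was therefore the only value per peak, as the design allowed for. The lists hold 1 combined set of intervals per antibody, so replicate error, sequencing depth and the IgG background could not be measured. Intervals below describe error over peaks or, where stated, over chromosome ends, neither of which are biological replicates. Each SD is over draws of moved positions. No test below compares conditions across replicates.

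Positions were read as BED intervals and are printed counting from 1. No peaks of a list overlapped each other (the smallest gap was 28 bp for ARID1B and 58 bp for ARID2). Peaks were called shared when they overlapped a peak of the other list by at least 1 bp; the overlap was computed with numpy, where bedtools had been planned. The observed overlap was set against 1000 draws in which all ARID2 peaks of a chromosome were moved together, circularly, by a random distance within the span of both lists. This keeps spacing and widths, but it does not exclude centromeres or other stretches without mappable reads, so it understates the overlap expected between any sets of open sites. The smallest p these draws can give is 0.001. Differences in median width were tested with a two-sided permutation test of 100000 resamples (smallest p 1e-05) and given with a 95% bootstrap interval from 1000 resamples. Shares of peaks carry 95% Wilson intervals. Shares between chromosomes were compared with two-sided Fisher's exact tests, and windows of 1 Mb with at least 10 peaks with two-sided exact binomial tests, both with Benjamini-Hochberg adjustment and a threshold of 0.05. These tests treat peaks as independent, although neighbouring peaks cluster. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

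The overlap code was tested on simulated lists with the real widths. With 20% of 7642 ARID1B peaks planted in the ARID2 list it returned 20.3%, and with none planted it returned 0.445% against a chance mean of 0.448%. The planted peaks were near copies of ARID1B peaks, so this checked the code alone. The chromosome test found a doubled chromosome 17 in 100% of simulated pairs of 7661 peaks and called 1% of the other chromosomes. Its simulated peaks were drawn independently, so this rate does not carry over to the clustered peaks of the lists.

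The overlap of the lists, the widths of shared peaks and the regions to name were fixed before the data were examined. Regions were named by a fixed rule, the 10 widest peaks on the standard chromosomes in each of 3 classes (shared, ranked by the sum of the width ranks in both lists; ARID1B list only; ARID2 list only). The comparison of chromosomes, the 1 Mb windows, the chromosome ends and the name numbers were chosen after the lists had been examined. The test of peak width between the lists was not planned. Alternatives were a reciprocal overlap of 50%, a distance of 1 kb, the midpoint in place of any base, equal numbers of the widest peaks, standard chromosomes alone, uniform placement, local shifts of 20 to 200 kb, joined neighbours and the removal of peaks near chromosome ends. The midpoint, the local shifts, the joined neighbours and the removal near ends were added after the data had been examined. Tests that assign peaks to promoters and genes, and 28 fixed gene lists, were planned but not run, because no annotation of hg19 was used here; the gene table at hand is for GRCh38, and positions were not converted between builds. Peaks are therefore identified by position, without gene names, and the parts of the naming rule that list members of gene lists and chosen genes were left out. Alternatives that need an IDR for each peak were not run either.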

Results

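The binding sites of ARID1B and ARID2 were mapped by CUT&Tag in MOLM13, an established human acute myeloid leukaemia cell line that carries a KMT2A fusion gene. ARID1B is a subunit of the canonical BAF chromatin remodelling complex, and ARID2 is a subunit of the related PBAF complex. The complexes share most of their other subunits, including the ATPase. The comparison of the lists asks which sites carry either subunit and which carry both. Each antibody was represented by 2 libraries, combined by the authors into 1 peak list, and the labels tie 2 IgG control libraries to both lists. No replicate values accompany the peaks, so no error below measures variation between replicates.

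The ARID1B and ARID2 lists were of similar size, and ARID1B peaks were the wider. The ARID1B list held 7756 peaks, which covered 6.40 Mb of hg19. The ARID2 list held 8146 peaks, which covered 5.94 Mb. The median width was 730 bp for ARID1B (quartiles 532 and 1021 bp) and 632 bp for ARID2 (quartiles 459 and 894 bp). The difference of 98 bp (95% bootstrap interval 84.5 to 113) passed a two-sided permutation test over peaks (p = 1e-05, the smallest it can give). This test was not planned and its units are peaks of 1 list per antibody. It cannot tell a difference between the antibodies from one of libraries, depth or peak calling. ARID1B peaks ranged from 234 to 6400 bp and ARID2 peaks from 222 to 11979 bp. The median distance between neighbouring peaks was 125 kb in the ARID1B list and 141 kb in the ARID2 list. Standard chromosomes held 7661 ARID1B and 8075 ARID2 peaks. The remaining 95 ARID1B peaks (1.22%) and 71 ARID2 peaks (0.872%) lay on unplaced, unlocalised or alternate contigs, and neither list had a mitochondrial peak.

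A minority of the sites in either list carried a peak of the other subunit. In the ARID1B list, 2687 of 7756 peaks (34.6%, 95% Wilson interval 33.6 to 35.7) overlapped an ARID2 peak. In the ARID2 list, 2695 of 8146 peaks (33.1%, interval 32.1 to 34.1) overlapped an ARID1B peak. The remaining 5069 ARID1B peaks and 5451 ARID2 peaks had no counterpart. Shifted positions gave 48.4 ± 6.48 shared ARID1B peaks (SD over 1000 draws, 0.624% of the list) and 49.2 ± 6.60 shared ARID2 peaks (0.604%). The observed overlap was 55.5 times the shifted mean for ARID1B and 54.8 times for ARID2 (one-sided permutation p = 0.001, the smallest the draws can give, for both). When ARID2 peaks were moved by only 20 to 200 kb, which keeps regional density, the ARID1B overlap was 40.0 times the mean of the draws and the ARID2 overlap 39.7 times. Neither kind of draw keeps peaks at open sites, so a preference of both lists for open chromatin counts as overlap in these multiples. The planned test with promoters as background was not run.

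Where the lists met, the peaks were nearly centred on each other. The 2715 overlapping pairs had a median distance of 117 bp between midpoints, with an upper quartile of 243 bp. They shared 1.73 Mb, which was 27.0% of the bases in ARID1B peaks, 29.1% of those in ARID2 peaks and 16.3% of the bases covered by either list. The ARID1B peak was the wider of the pair in 59.1% of cases. In 35.7% of pairs the ARID2 peak lay entirely inside the ARID1B peak, and in 23.6% the ARID1B peak lay entirely inside the ARID2 peak. Widths within pairs correlated moderately across pairs (Spearman rho 0.31, Pearson r 0.32 on log2 widths, permutation p = 0.001 for rho, the smallest it can give); pairs are not independent replicates. The nearest ARID2 peak lay a median of 85.7 kb from an unshared ARID1B peak, and the nearest ARID1B peak lay 107 kb from an unshared ARID2 peak. Within 10 kb of the other list lay 11.3% of unshared ARID1B peaks and 9.52% of unshared ARID2 peaks, against 5.38% and 5.20% of the non-overlapping peaks over the shifted draws. Local moves of 20 to 200 kb, added after the data had been examined, gave 8.23 ± 0.35% and 7.83 ± 0.318% (SD over draws), so regional density made up part of the excess (one-sided permutation p = 0.001 against the local moves, the smallest the draws can give, for both).

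**Figure D1:**
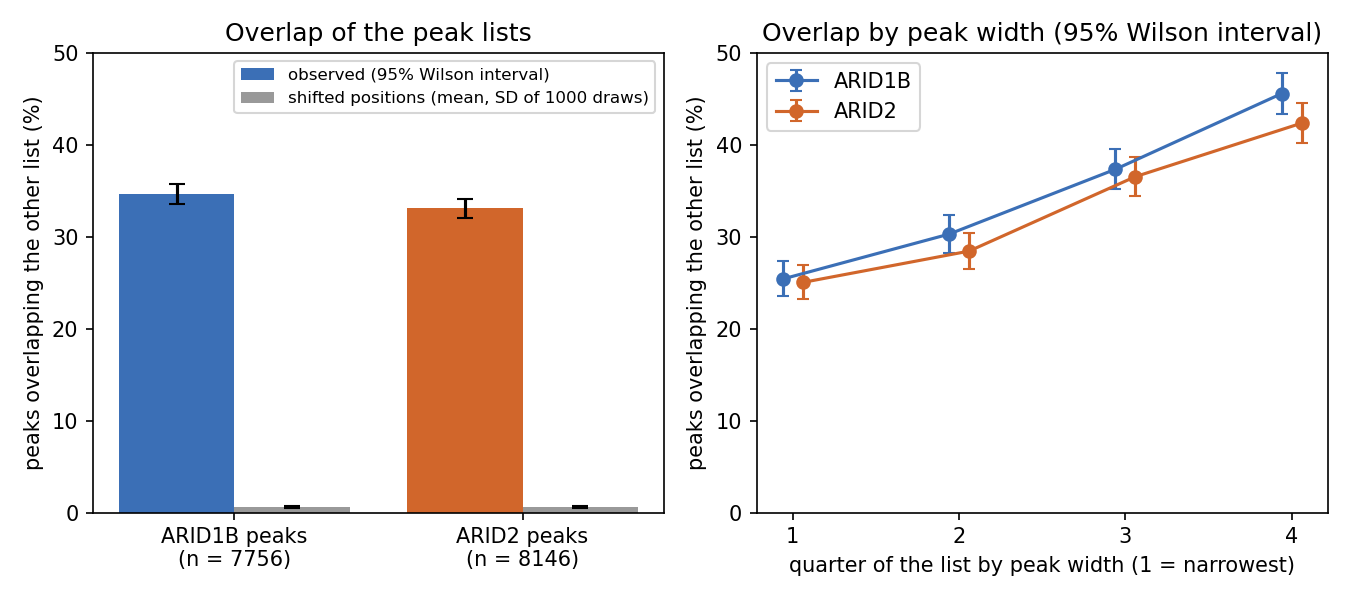
Left, percent of ARID1B (blue) and ARID2 (orange) peaks that overlap the other list, with 95% Wilson intervals, beside the mean and SD of 1000 shifted draws (grey). Right, the same percent (y axis) in 4 equal groups of a list by peak width (x axis), narrowest to widest.

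Shared peaks were wider than peaks found with 1 antibody alone. Shared ARID1B peaks had a median width of 826 bp, against 686 bp for ARID1B-only peaks, a difference of 140 bp (95% bootstrap interval 119 to 161). Shared ARID2 peaks had a median width of 711 bp, against 599 bp for ARID2-only peaks, a difference of 112 bp (interval 88 to 132). Both differences passed a two-sided permutation test over peaks (p = 1e-05, the smallest it can give). The shared percent went from 25.4% in the narrowest of 4 equal groups of the ARID1B list (234 to 532 bp) to 45.6% in the widest (1022 bp or more). In the ARID2 list it went from 25.04% (222 to 459 bp) to 42.4% (894 bp or more). A wide peak meets any other list more readily, and the few overlaps of the shifted draws showed a gap of 135 ± 67.4 bp for ARID1B and 144 ± 65.9 bp for ARID2 (SD over draws). The observed gaps were not larger than these (one-sided permutation p = 0.48 for ARID1B and 0.70 for ARID2). The draws held means of 48.4 shared ARID1B and 49.2 shared ARID2 peaks, against 2687 and 2695 observed. Such meetings are a small part of the observed overlap, so this comparison cannot decide how much of the gap width alone made. With the midpoint of the peak required to lie inside the other peak, which takes its own width out of the criterion, the gap was 81.5 bp for ARID1B and 87 bp for ARID2 (permutation p = 0.0001, the smallest it can give, for both).

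The widest shared sites were spread over 8 chromosomes. The first by joint rank lay on chromosome 18, where an ARID1B peak of 5580 bp (105230 to 110809) enclosed an ARID2 peak of 2774 bp (105823 to 108596). On chromosome 5 an ARID1B peak of 2854 bp (109024266 to 109027119) and an ARID2 peak of 2343 bp shared 2314 bp. Chromosome 3 held 3 of the 10 sites. At 143689854 to 143692096 the ARID1B peak of 2243 bp lay inside an ARID2 peak of 2318 bp, and at 152878183 to 152880281 peaks of 2099 bp (ARID1B) and 2156 bp (ARID2) shared 1938 bp. Another site, at 197825837 to 197832236, was the widest ARID1B peak of all at 6400 bp and held an ARID2 peak of 1754 bp. The other sites lay on chromosomes 1, 2, 4, 9 and 22. Of the 10 sites, 3 were within 2 Mb of a chromosome end. These sites and those named below were not screened here for repeats, low mappability or signal in the IgG libraries. Background common to both antibodies was therefore not told apart from shared binding.

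The widest ARID1B-only and ARID2-only sites differed in where they lay on the chromosomes. The 10 widest ARID1B-only peaks measured 2648 to 3155 bp, lay on chromosomes 2, 3, 5 and 8, and none was within 2 Mb of a chromosome end. The widest was on chromosome 3 at 194206165 to 194209319 (3155 bp), with the nearest ARID2 peak 249 kb away. It was followed by peaks on chromosome 2 at 233945762 to 233948892 (3131 bp, 20.5 kb away) and chromosome 3 at 128134325 to 128137306 (2982 bp, 262 kb away). A peak of 2669 bp on chromosome 2 (66803094 to 66805762) was 819 kb from any ARID2 peak, and one of 2648 bp on chromosome 3 (177075828 to 177078475) was 1962 kb away. The 10 widest ARID2-only peaks measured 3667 to 11979 bp, and 8 of them lay within 2 Mb of a chromosome end. The widest ARID2 peak of all, 11979 bp on chromosome 2 (241397666 to 241409644), had its nearest ARID1B peak 95.8 kb away. On chromosome 10 ARID2-only peaks of 6645 bp (134600346 to 134606990) and 3916 bp (135253547 to 135257462) were among the 10. Chromosome 5 held 4 of them, of 6396 bp (668570 to 674965), 5487 bp (1052989 to 1058475), 3675 bp (320397 to 324071) and 3667 bp (370988 to 374654). The others lay on chromosomes 17 and 21. Around the chromosome 5 sites, the first Mb of the chromosome, a region singled out after its values were seen, held 56 ARID2 peaks, with a median gap of 3.88 kb, and 4 ARID1B peaks. Of these, 3 in each list overlapped the other list. With peaks of a list within 10 kb joined, 16 ARID2 and 4 ARID1B clusters were left in this Mb, and the contrast no longer passed (adjusted p = 0.27, exact binomial test over 1 Mb windows).

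**Figure D2:**
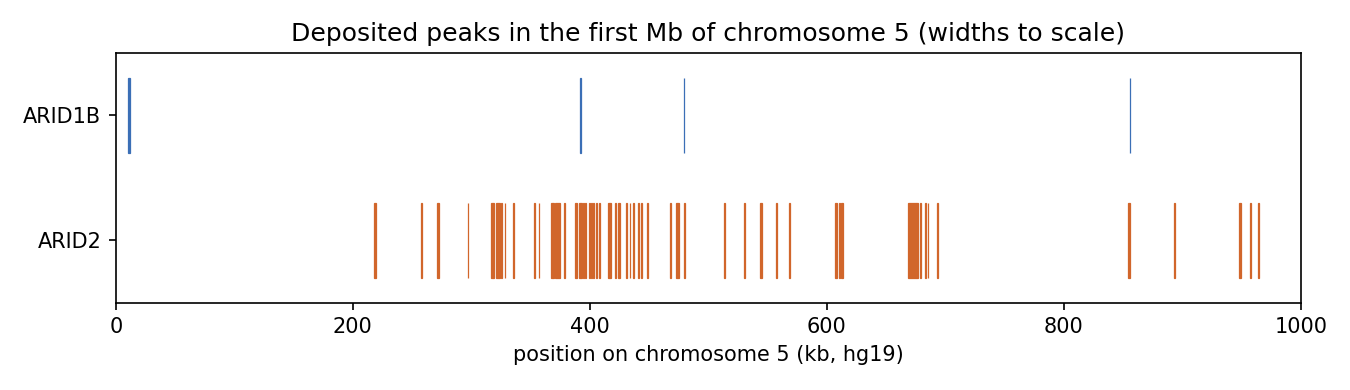
Deposited ARID1B (blue) and ARID2 (orange) peaks over the first Mb of chromosome 5 of hg19 (x axis, position in kb), each drawn as a box of its width. The 56 ARID2 peaks lie between 217857 and 964843 bp, and 4 ARID1B peaks fall in the same Mb; with peaks within 10 kb joined, the clusters number 16 and 4.

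The lists were distributed differently over the chromosomes. Of 24 chromosomes, 11 held a different share of the ARID1B list than of the ARID2 list (two-sided Fisher's exact test, Benjamini-Hochberg adjusted). Chromosomes 5, 8, 11, 15, 18, 19 and X held a larger share of ARID2 peaks, and chromosomes 1, 6, 12 and 17 a larger share of ARID1B peaks. Chromosome 17 held 267 ARID1B peaks (3.49% of the list) and 180 ARID2 peaks (2.23%; adjusted p = 5.6e-05, Fisher's exact test). Chromosome 11 held 284 ARID1B peaks (3.71%) and 411 ARID2 peaks (5.09%; adjusted p = 0.00032, Fisher's exact test). Chromosome X held 120 (1.57%) and 197 (2.44%; adjusted p = 0.00055, Fisher's exact test). The test counts clustered peaks as independent. With peaks of a list within 50 kb joined, 3 chromosomes differed (11, 17 and X). The log2 ratio of shares, ARID2 over ARID1B, then went from 0.212 to -0.0021 on chromosome 5, from 0.233 to 0.0997 on chromosome 8 and from 0.401 to 0.101 on chromosome 19. On chromosome 15 it was 0.319 before and 0.343 after joining (adjusted p = 0.097, Fisher's exact test), so the call ended there without a smaller contrast. The ratio was also smaller on chromosome 18 (0.617 to 0.375) and nearer 0 on chromosomes 1 (-0.27 to -0.13), 6 (-0.304 to -0.123) and 12 (-0.363 to -0.23). Without peaks within 2 Mb of a chromosome end, chromosomes 5 and 19 no longer passed, while 9 and 13 did. The log2 ratio was then 0.0889 on chromosome 5. On chromosome 19 it was 0.315 (adjusted p = 0.08, Fisher's exact test), so most of that contrast stayed.

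The density of peaks and the extent of sharing also differed among chromosomes. ARID1B peaks were densest on chromosome 6 (3.97 per Mb up to the last peak) and ARID2 peaks on chromosome 8 (3.97 per Mb). By this measure chromosome Y (0.372 and 0.389 per Mb) and chromosome X (0.775 and 1.27 per Mb) held the fewest, and chromosome 14 (1.29 and 1.40 per Mb) the fewest among the autosomes. The length was counted from the first base, so it includes stretches without mappable reads. This lowers the density of chromosomes such as Y and 14, and their rank may depend on it. Copy number was not taken into account. Sharing was lowest on chromosome 19, where 14.3% of 161 ARID1B peaks (95% Wilson interval 9.71 to 20.5) and 10.3% of 224 ARID2 peaks (interval 6.94 to 14.9) were shared. Both lay below the rest of their list (adjusted p = 8.2e-08 and 3.5e-14, Fisher's exact test). On chromosome 17 the shared percent of ARID1B peaks was 18.7% (interval 14.5 to 23.8, adjusted p = 8.2e-08, Fisher's exact test). That of ARID2 peaks was 27.8% (adjusted p = 0.21, Fisher's exact test). On chromosome 8 it was 46.5% for ARID1B (interval 42.015 to 51.006, adjusted p = 4.5e-07, Fisher's exact test) and 37.9% for ARID2 (adjusted p = 0.022, Fisher's exact test). On chromosome 6, 44.6% of ARID2 peaks were shared (interval 40.6 to 48.6, adjusted p = 1.9e-08, Fisher's exact test) and 37.8% of ARID1B peaks (adjusted p = 0.21, Fisher's exact test). Shared peaks numbered 50 in both lists on chromosome 17, and 256 (ARID1B) and 258 (ARID2) on chromosome 6. The departure in 1 list alone there went with the unequal peak numbers of the lists. In all, the shared percent departed from the rest of the list on 5 chromosomes for ARID1B and on 11 for ARID2. These tests also count clustered peaks as independent, and they were not repeated with joined peaks.

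**Figure D3:**
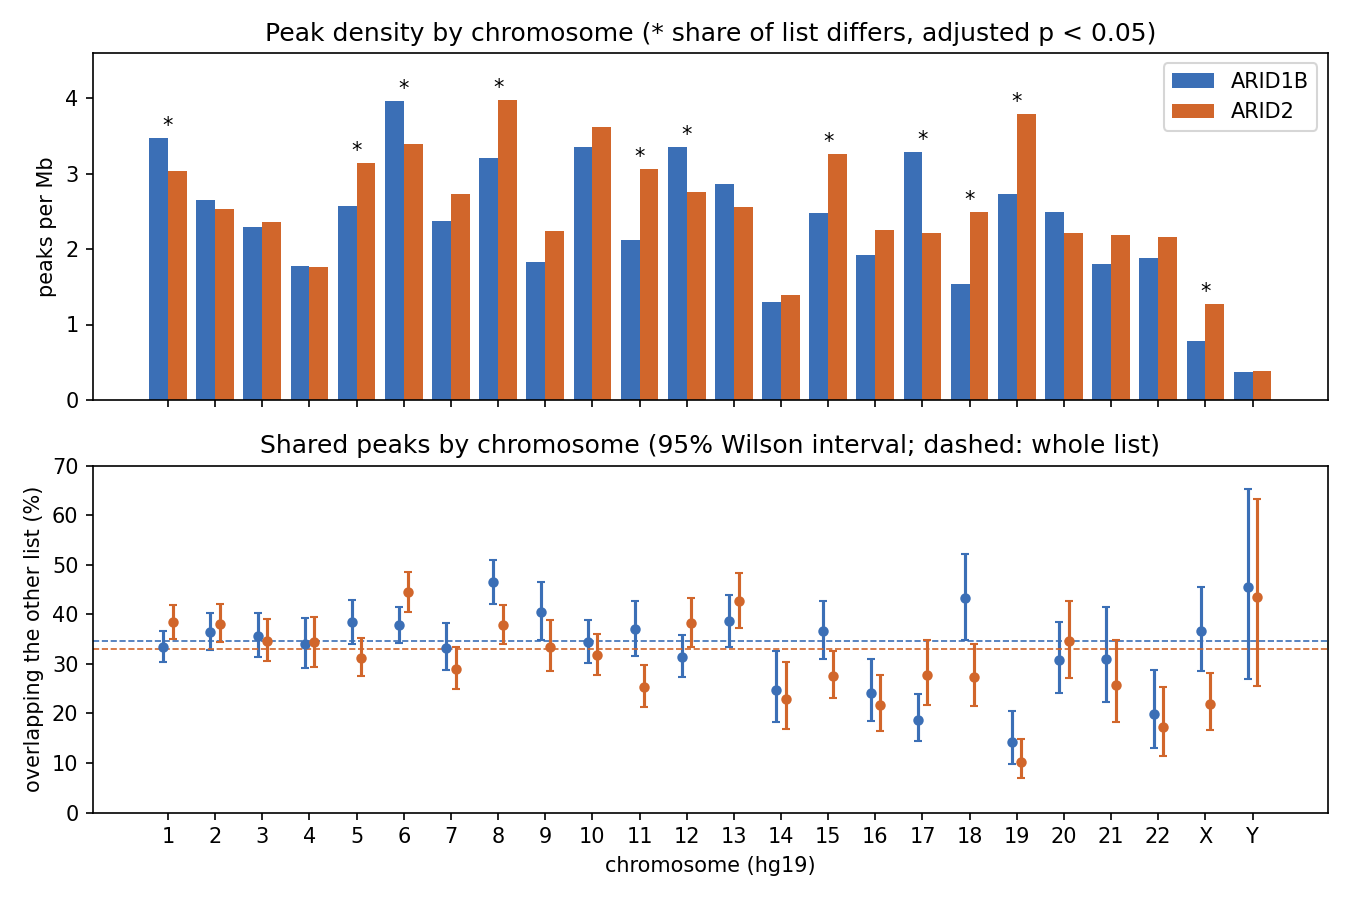
Top, ARID1B (blue) and ARID2 (orange) peaks per Mb on each chromosome, with asterisks on the 11 chromosomes whose share of the lists differed (adjusted p under 0.05, Fisher's exact test). Bottom, percent of peaks on each chromosome that overlap the other list, with 95% Wilson intervals and dashed lines for the whole lists; chromosome 19 lies lowest in both lists.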

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

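The name numbers were taken up after the lists had been examined, and the 2 tests of ARID1B-only peaks against the ARID2 numbers were chosen only after their result was seen.

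The name column, which the comparisons above do not use, carries a signal of its own. Peak names in each list end in a number that rises in genome order in 100% of lines, with gaps. The ARID1B numbers run from 5 to 18763 over 7756 peaks, so 11007 numbers below the highest are missing and 41.3% are present. The ARID2 numbers run from 1 to 10732 over 8146 peaks, so 2586 are missing and 75.9% are present. Of 3275 names found in both lists, 0 are at overlapping positions, so each list was numbered on its own.

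A candidate explanation is that each list was numbered before it was filtered and that a missing number is a removed peak. This predicts more missing numbers between neighbours that lie farther apart, which held: Spearman rho across gaps was 0.60 in the ARID1B list and 0.29 in the ARID2 list, where gaps are not independent replicates. The longest 25% of gaps lacked a mean of 2.93 ARID1B numbers and 0.575 ARID2 numbers. If this reading is right, 41.3% of numbered ARID1B peaks and 75.9% of numbered ARID2 peaks passed. Whether the antibody, the libraries or the threshold set this difference was not tested.

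On the same reading, the numbers bound how many peaks of 1 list alone could have lost their partner to the filter. Of the ARID1B-only peaks flanked by ARID2 peaks on both sides, 2980 of 4966 (60.0%, 95% Wilson interval 58.6 to 61.4) lay between ARID2 peaks with consecutive numbers, where on this reading no ARID2 peak was removed, which argues against removal as the cause of these. The other ARID1B-only peaks stay open. Draws moved by 20 to 200 kb gave a mean of 61.7% between consecutive numbers (lowest of 1000 draws 60.2%). The observed value lay just below every draw (one-sided permutation p = 0.001, the smallest the draws can give), so some may sit on removed ARID2 peaks. For ARID2-only peaks, 849 of 5325 (15.9%) lay between ARID1B peaks with consecutive numbers, against a median of 16.9% over the shifted draws (lowest 14.03%) and a mean of 15.5% for local moves, which leaves removal of ARID1B partners open for the rest because so many ARID1B numbers are missing. If each removed peak met at most 1 peak of the other list, and peaks beyond the outermost peak of the other list are left open, at most 49.6% of ARID1B peaks and 77.3% of ARID2 peaks could have been shared before filtering, against the 34.6% and 33.1% observed.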

How the results depend on the processing

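In 33 alternatives the result was counted as unmoved. They concerned the peak counts, the overlap, the widths, the chromosome ends, the windows of 2 Mb and the chromosomes without their end zones. This tally is not a measure of robustness. The peak counts have no threshold to cross. Without end zones 11 chromosomes differed again, but not all of them were the same. The shared percent of ARID1B peaks ranged from 25.6% (reciprocal overlap of 50%) to 35.8% (within 1 kb). That of ARID2 peaks went from 24.3% to 34.2% under the same settings and was highest, 34.8%, without peaks within 2 Mb of a chromosome end. Among 3878 widest peaks of each list it was 27.6% and 27.7%. The multiple over chance depended more on the setting than the percent did, from 28.4 (within 1 kb) to 144 (reciprocal overlap) for ARID1B, while the permutation p stayed at 0.001. The width gap stayed above 0 under each alternative, between 78.5 and 141 bp for ARID1B and between 87 and 144 bp for ARID2. Merging overlapping peaks changed nothing, since none overlap. The added settings were chosen after seeing the data. Among these, joining peaks within 50 kb lowered the chromosomes that differed from 11 to 3, and joining peaks within 10 kb lowered the 1 Mb windows that differed from 25 to 2; joining leaves fewer peaks to count. No paired analysis was possible because the lists carry no values per replicate, and for the same reason no replicate could be left out. Alternatives that need an IDR per peak, another score column, promoters or genes were not run. Depth per library is unknown, so a site missing from a list cannot be called unbound.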

Other observations

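The comparisons in this part were chosen after the lists had been examined, and its tests, other than that of joined peaks at chromosome ends, only after the result was seen.

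ARID2-only peaks crowded near chromosome ends, far more than ARID1B-only peaks. Ends were taken as the first base of the chromosome or the last peak of either list, without chromosome Y and the short arms of 13, 14, 15, 21 and 22. Within 2 Mb of these 41 ends lay 546 of 5402 ARID2-only peaks (10.1%, 95% Wilson interval 9.33 to 10.9). The same zones held 171 of 4993 ARID1B-only peaks (3.42%, interval 2.96 to 3.97) and 80 shared ARID2 peaks (3.02%), and they make up 2.71% of the length scanned. ARID2-only peaks outnumbered ARID1B-only peaks at 31 ends and were outnumbered at 7 (two-sided permutation test swapping the lists at each end, p = 2e-05). The start of chromosome 5 (68 against 3), the end of chromosome 10 (53 against 5), the start of chromosome 4 (34 against 1), the end of chromosome 18 (33 against 1) and the end of chromosome 19 (27 against 0) had the largest excess. At the start of chromosome X the order was the other way, with 6 ARID1B-only peaks and 0 ARID2-only peaks. ARID2-only peaks in these zones were also wider than elsewhere, with a median of 726 bp against 586 bp (difference 140 bp, 95% bootstrap interval 91 to 189, permutation p = 1e-05, the smallest it can give). ARID1B-only peaks measured 682 bp and 686 bp.

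Single windows of 1 Mb were also compared. Of 527 windows with at least 10 peaks, 25 departed from the ratio of the lists (exact binomial test, adjusted), 17 towards ARID2 and 8 towards ARID1B. Of these, 9 touched an end zone, all towards ARID2, and the other 16 were 8 towards each subunit. The windows named here were picked after their values were seen. With peaks of a list within 10 kb joined, 2 windows passed, both in end zones and towards ARID2: the Mb of chromosome 19 starting at 58000001 (19 against 0 before and after) and the first Mb of chromosome 4 (18 against 0 before, 16 against 0 after). No window away from the ends, and none towards ARID1B, passed after joining. Some of these kept most of their contrast and fell just short. On chromosome 19 the Mb starting at 12000001 and that starting at 37000001 went from 13 ARID2 and 0 ARID1B peaks to 12 and 0 clusters (adjusted p = 0.055 for both, exact binomial test). On chromosome 12 the Mb starting at 123000001 went from 12 ARID1B and 0 ARID2 peaks to 10 and 0 (adjusted p = 0.057, exact binomial test). Chromosome 21 between 45000001 and 46000000 went from 29 ARID2 and 3 ARID1B peaks to 15 and 2 (adjusted p = 0.17, exact binomial test), with fewer clusters to count. In the first Mb of chromosome 5 joining took away most of the contrast, from 56 ARID2 and 4 ARID1B peaks to 16 and 4 (adjusted p = 0.27, exact binomial test).

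A few technical readings of the chromosome-end pattern were tested. Splitting of broad regions into many peaks, as far as a join of 10 kb undoes it, is argued against as the whole cause. With peaks within 10 kb joined, the share of ARID2-only clusters in the end zones was 2.34 times that of ARID1B-only clusters (95% interval over ends 1.69 to 3.27). For single peaks it was 2.95 times (interval 1.97 to 4.36). Wider joins were not tried at the ends. Removal of ARID1B peaks before deposit was read from the name numbers, allowing each removed peak to meet 1 ARID2-only peak. At most 316 ARID2-only peaks could have been shared in this way, against an excess of 375 ARID2-only over ARID1B-only peaks. Removed ARID1B peaks that met no ARID2 peak would also lower the excess. They were not counted, so 316 is not an upper limit on what removal could cover. In the first Mb of chromosome 5 only 7 ARID1B numbers are missing between its 4 peaks. Over all ends, removal therefore stays open as the whole cause or as part of it. Splitting and removal acting together were not tested and stay open. A bias of tagmentation, mapping or copy number of equal strength in the libraries of both antibodies would raise all ARID1B peaks in the zones as much as all ARID2 peaks. In the deposited lists their share was 1.21 times that of the length for ARID1B (95% interval over ends 0.948 to 1.48) and 2.87 times for ARID2 (interval 2.05 to 3.79). The ratio was 2.38 (interval 1.71 to 3.25). This comparison cannot decide the question, because 546 of the 626 ARID2 peaks in the zones are the ARID2-only peaks that showed the pattern. Peaks removed before deposit, perhaps more in 1 list than in the other, are not counted either. A bias of equal strength and a bias that acts more strongly in the ARID2 libraries both stay open. Also open are a background specific to the ARID2 libraries, base composition, which was not analysed here without the hg19 sequence, and, as an untested hypothesis, a real preference of ARID2 for these regions. The IgG libraries, which bear on background, were not analysed here.

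Other zone sizes gave the same direction, with ratios of 3.78 (1 Mb) and 2.14 (5 Mb), and without the start of chromosome 5 the ratio was 2.63. The 7 alternate haplotype contigs of chromosome 6, which are alternative versions of the MHC region and share reads with it, held 47 ARID1B peaks and 7 ARID2 peaks (adjusted p = 1.8e-08, Fisher's exact test). These peaks can repeat the same sites. They are therefore not independent counts, and the p can overstate the contrast. The unplaced contigs held 39 ARID1B peaks, 27 of them shared, and 58 ARID2 peaks, 31 of them shared. Most lay on chrUn_gl000225 (21 ARID1B peaks, 17 shared, and 36 ARID2 peaks, 20 shared) and chrUn_gl000216 (9 ARID1B peaks, 8 shared, and 13 ARID2 peaks, 9 shared). Background common to both antibodies was not told apart from shared binding on these contigs.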
